A study of Mus musculus with 908 samples.

How the data were processed

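The material was single tumour cells from mouse skin squamous cell carcinoma, sorted by flow cytometry, with each sequenced library made from 1 well by the Smart-seq2 full-length protocol. By the strain names in the labels, tumours analysed before therapy carried an inducible activated Hras transgene and a SMAD-binding-element mCherry reporter, which reads out TGF-beta signalling. Those analysed after adoptive cell transfer, an immunotherapy in which immune cells are infused, carried the Hras transgene together with an inducible ovalbumin antigen and a constitutive mCherry. All gates excluded cells with CD45, CD117, CD140a and CD31 at the surface.

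The deposited values were TPM, a length-normalised share of each library's transcripts, per gene and library, in 1 table of 362 libraries labelled before therapy and 1 table of 546 libraries labelled after therapy. The submitters' processing notes list Bowtie2 2.2.9, RSEM 1.2.30 and the mouse build mm10. How multi-mapping reads and spike-ins were handled is not given in the sources used here. TPM keeps no read depth, so the number of genes at a TPM of at least 1 stood in for the depth of each library, and no read-based interval could be given. The tables held 46517 gene rows and 92 rows of ERCC spike-in RNA. Of the gene identifiers, 46005 matched the GENCODE M21 annotation of the same build, which gave symbols and coordinates, and 512 did not. A further caution concerns ribosomal RNA. A set of 8 rows, treated together as ribosomal, took a median of 68.0% to 76.6% of the TPM per plate name. The set includes the protein-coding gene Lars2 and Gm15662, which did not match the annotation. TPM of all other genes are shares of what these rows left.

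Libraries with at least 2000 genes at a TPM of at least 1 were used, which kept 696 of 908 and left out 212. Among all 908 wells, 47 had over 50% of their TPM in spike-ins. The labels name plates but no animal or culture, so cells were not treated as replicates and each of the 5 groups was 1 sample. No test, p-value or standard error was computed between groups.

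Pearson correlation of log2(TPM + 1) between all kept libraries was used to find cells sequenced more than once. A pair was taken as 1 cell when each library was the other's best match by a margin of at least 0.05 in r, or when r was at least 0.88. These limits were set after the correlations had been seen. The search found 246 pairs among 481 libraries, and the other 241614 pairs had a median r of 0.62 and a maximum of 0.85. By the rule none of these others can reach 0.88. Pairs called by the margin went down to an r of 0.67, below the 99th percentile of the others (0.77), so the ranges overlap. Of the 246 pairs, 131 joined libraries of the same group and 115 joined a library labelled before therapy with one labelled after therapy. Libraries paired within a group were averaged and counted once as 1 cell. They include 1 pair in different wells of the same plate name in each of the CD44+, CSC1 and α6-negative plates. Wells were sorted singly, so these may be different cells. Libraries of the plates named OT_C and OT_D, of whose kept libraries 71 of 72 and 41 of 45 paired with libraries labelled before therapy, were left out of the group after therapy, because their cells already counted before therapy and the same cell cannot be in both groups. The files do not settle which label is right. On the reporter-positive plates, 72 of 73 kept libraries of CSC1 and 26 of 32 of CSC2 had a partner labelled after therapy. So had 15 of 15 of the CD44+ reporter-negative gate, and no alternative left all of these libraries out. Leaving out OT_C and OT_D departs from the design fixed beforehand, and values with all libraries as labelled are given beside the results. Tested on simulated data, the search found 60 of 60 simulated repeat pairs and 0 false ones. The simulated repeats were single profiles redrawn with Poisson noise alone, so this gives no error rate for real repeats.

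The groups then held 104 reporter-positive cells (72 and 32 on plates CSC1 and CSC2), 14 CD44+ reporter-negative cells, 91 CD44-negative α6+ cells, 42 α6-negative cells and 198 cells after transfer (100 on OT1/OT_B and 98 on OT2/OT_A, where each pair of plate names held repeat libraries of the same cells). The median number of genes per kept library was 7769 on CSC1, 7575 on CSC2, 7222 in the CD44+ gate, 6810 in the CD44-negative α6+ gate, 5521 in the α6-negative gate and 6079, 6885, 6836 and 6284 on OT1, OT2, OT_A and OT_B. The median share of spike-in TPM was 2.78% in the α6-negative gate and 0.11% to 0.61% on all other plate names.

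For each comparison, a fold is the ratio of mean TPM plus a pseudocount of 1, so it understates changes of weakly expressed genes. A minority of cells with high values can set such a mean, so a fold need not describe most cells of a group. Outside the alternatives, no fold is given against a group listed at 0. A transcript was called detected at a TPM of at least 1, and shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. For 18 gene lists (TGF-beta and SMAD response; epithelial-mesenchymal transition and stem-like carcinoma; glutathione and NRF2 targets; basal keratinocyte; suprabasal keratinocyte; stress keratins and alarmins; S phase; G2/M; T cell co-signalling ligands and immunosuppressive factors; MHC class I; interferon response; MHC class II; chemokines and cytokines; hypoxia and glycolysis; immediate early genes; p53 targets and cyclin-dependent kinase inhibitors; extracellular matrix and proteases; sort gate transcripts), the median log2 fold was taken over members with a mean TPM of at least 1 in either group. Its percentile among 10000 random lists of equal size, matched in 20 bins of mean expression, describes these libraries and is not a test. The list members Il36a, Il36g and Vsir stand in the tables under older symbols (Il1f6, Il1f9 and 4632428N05Rik), and Nectin2 under Pvrl2, which the list also held and which counted once. They were matched by identifier or synonym only after the medians had been seen, which moved the co-signalling median of α6+ over α6-negative cells from -0.52 to -0.78, turned that of reporter-positive over CD44+ reporter-negative cells from 0.060 to -0.098, and moved the stress keratin median of cells after transfer over CD44-negative α6+ cells from 1.06 to 0.86. Genes of close families (Krt6a and Krt6b, the Sprr, Stfa and H2 genes) can share reads, so their levels are uncertain. The lists treated as leading results among the alternatives were chosen after the medians had been seen. Members are counted as higher or lower when their fold was at least 2.

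Genes were named by a rule fixed before the data were examined. It took the 10 highest and 10 lowest folds per comparison among genes with a mean TPM of at least 10 and detection in at least 25% of cells of the higher group, the same direction in detection and in mean log2(TPM + 1), and at least a 2-fold difference on every plate of a group. Predicted, mitochondrial and ribosomal protein genes and pseudogenes were passed over. Cd80, Cd274, Cd34, Cd44, Itga6, Hras, Tgfb1, Mki67, Cdkn1a and members of the gene lists could also be named. Cell types were read from fixed marker sets, by the set with the highest mean log2(TPM + 1) in each cell, and no doublet caller was run because wells were sorted singly.

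Resemblance of cells after transfer to the gates before it was read by Spearman correlation with each gate's mean profile over the 100 most distinctive genes per gate (389 in all), with cells from before therapy left out of their own gate. Cells after transfer were clustered on 2000 variable genes, 20 components, 15 neighbours and Leiden resolution 0.5. Libraries were called for sex by Xist or by Y-linked transcripts at a TPM of at least 10. The window of 3000 to 6000 genes was applied to single libraries before repeats were merged, whereas Cd80 was counted by the number of genes in the merged profile of each cell. The alternatives covered the cell filter, cells of other types, the gene-number window, pseudocounts of 0.1 and 10, means of logs, list membership, rescaling, detection limits, plates left out in turn, gene number and correlation of the resemblance step, and cluster settings. Added after the data were seen were the labels as deposited, unmerged repeats, removal of ribosomal rows, the plates of cells after transfer left out as merged, and subsets by sex transcript or by cell type and gene number together.

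The fold and list steps were tested on simulated data, in which cells were drawn from the second group of each comparison and 200 genes were changed by known folds. Only genes with a mean TPM of at least 10 in that second group entered. The step ran on 4208 genes for reporter-positive against CD44+ reporter-negative cells, 3783 in each of the 3 comparisons against CD44-negative α6+ cells, 4628 for α6+ against α6-negative cells and 4044 for cells after transfer against reporter-positive cells. Genes made 4-fold higher came back with a median log2 fold of 1.89 to 2.04 over the 6 comparisons, and genes made 2-fold higher with 0.92 to 1.06. Unchanged genes reached a 2-fold difference in 4.79% of cases for the reporter-positive against CD44+ reporter-negative cells, 4.16% for the CD44+ reporter-negative against CD44-negative α6+ cells, 4.90% for the α6+ against α6-negative cells, and 0.59% to 0.75% in the other 3 comparisons. List members were counted from a mean TPM of 1, and no rate was obtained for genes below 10. Both simulated groups came from the cells of 1 group, so no spread between plates or animals enters these rates. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.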

Results

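Single cells of mouse skin squamous cell carcinoma were profiled by full-length RNA sequencing before and after adoptive cell transfer, in a study of which tumour cells resist immune attack. Before therapy, 4 gates were sorted: reporter-positive cells (integrin α6+, CD34+, CD44+, with a TGF-beta-responsive mCherry), CD44+ reporter-negative cells (α6+, CD34-negative), CD44-negative α6+ cells without reporter or CD34, and α6-negative cells without any of these markers. After therapy, cells were sorted on mCherry without α6, CD34 or CD44. All gates excluded CD45, CD117, CD140a and CD31. Of 908 libraries, 696 had at least 2000 genes, with medians of 5521 to 7787.5 genes per plate name. Each group counted as 1 sample without replicates, since no animal is named, so the differences below are between these cells and carry no test.

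Many libraries were taken as repeats of 1 cell, and some of these carried different labels. By correlation of whole profiles, plate OT_C, labelled after therapy, shared 72 pairs of libraries with the reporter-positive plate CSC1, with a median r of 0.92. Plate OT_D shared 26 pairs with the other reporter-positive plate, CSC2, and 17 with the CD44+ reporter-negative plate. In 97.4% of the pairs across these labels both libraries had the same well name. OT_C and OT_D were left out of the cells after transfer. Which label is right is not settled, and 72 of 73 libraries of CSC1, 26 of 32 of CSC2 and 15 of 15 of the CD44+ reporter-negative plate had such a partner. Every comparison with these 2 gates therefore rests on their label before therapy. The groups then held 72 and 32 reporter-positive cells on CSC1 and CSC2, 14 CD44+ reporter-negative, 91 CD44-negative α6+ and 42 α6-negative cells, and 100 and 98 cells after transfer on OT1/OT_B and OT2/OT_A.

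**Figure D1:**
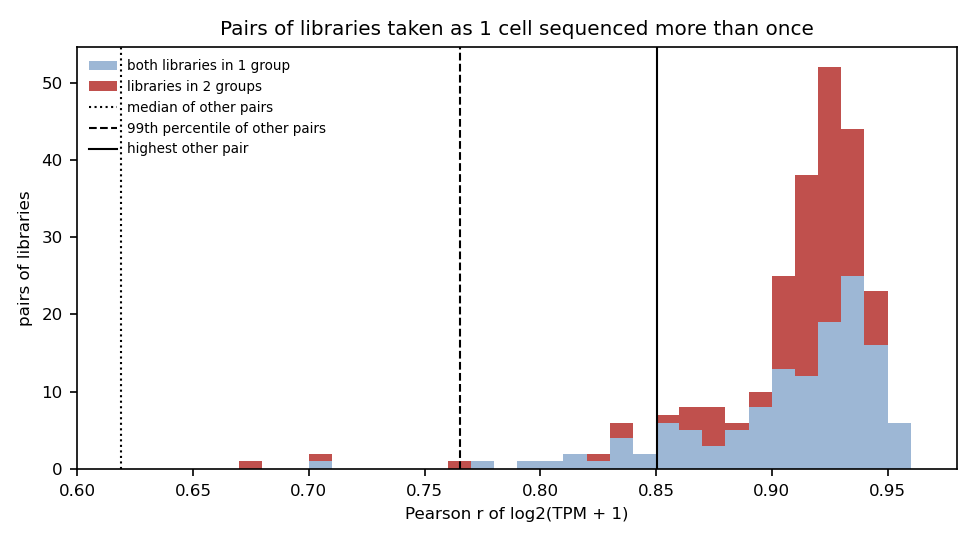
Number of library pairs taken as 1 cell (vertical axis) by the Pearson r of their log2(TPM + 1) profiles (horizontal axis), coloured by whether both libraries carry the same group label, with vertical lines at the median, the 99th percentile and the maximum of all other pairs. The other pairs had a median r of 0.62 and a maximum of 0.85, and the lowest called pair had an r of 0.67.

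Keratinocyte markers scored highest in every reporter-positive, CD44-negative α6+ cell and in every cell after transfer. Fibroblast markers led in 13 of the 42 α6-negative cells (30.95%, exact 95% interval 17.6 to 47.1) and pericyte or muscle markers in 3. Of 14 CD44+ reporter-negative cells, 11 were led by keratinocyte, 1 by fibroblast and 2 by pericyte or muscle markers. Xist, the transcript of the inactive X chromosome, marked 11 of 15 libraries of the CD44+ reporter-negative gate and Y-linked transcripts 0. The reporter-positive, α6-negative and after-transfer plates showed Y-linked transcripts and 0 libraries with Xist, while the CD44-negative α6+ gate held 23 libraries with Xist and 31 with Y-linked transcripts and 0 with both.

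Reporter-positive and CD44+ reporter-negative cells, which share α6 and CD44, were compared for what accompanies the reporter and CD34. The suprabasal list and that of stress keratins and alarmins were higher in reporter-positive cells, with medians of 1.44 (11 of 18 members at least 2-fold higher, although Krt1 and Krt10, the keratins of early differentiation, were lower) and 1.39 (7 of 11). Sprr1a, a cornified envelope precursor, averaged 598.7 against 3.05 TPM, Slpi, a secreted protease inhibitor, 260.8 against 0.859, S100a9, a calprotectin subunit, 488.2 against 16.5 and the stress keratin Krt16 2018 against 424.8. The gates differed in sex-linked transcripts, and within the CD44-negative α6+ gate cells with Xist over cells with Y-linked transcripts had medians of -1.62 for the suprabasal and -0.77 for the stress list, with S100a9 at 10.9 against 117.4 TPM. Stra6, the retinol uptake receptor, averaged 153.6 against 0.949 TPM and the tight junction gene Cldn4 75.996 against 0.414, while the protease gene Klk6 and the cornified envelope gene Cnfn, at 169.6 and 108.2 TPM, were listed at 0 in the other gate. Gsta1, a glutathione transferase, and Mmp9, a gelatinase, were 33.8-fold and 28.6-fold higher. Klk6 and Cnfn averaged 35.3 and 33.96 TPM on plate CSC1 and 471.7 and 275.1 on CSC2. Klk6 was detected in 31.7% and Cnfn in 29.8% of reporter-positive cells. Interferon-response genes were lower in reporter-positive cells, 21 of 23 by at least 2-fold, with a median log2 fold of -2.37. Ifi27l2a, an interferon-induced gene, averaged 0.108 against 327.4 TPM and Cd74, the MHC class II invariant chain, 4.31 against 107.96. MHC class II had a median of -3.76 (5 of 6 lower) and MHC class I of -1.05 (9 of 18 lower), with B2m, the class I light chain, at 333.6 against 799 TPM. Mitotic genes were lower too, 20 of 22, with a median of -1.67, and the proliferation marker Mki67 was detected in 23.1% of reporter-positive cells (15.4 to 32.4) and 85.7% of the others (57.2 to 98.2).

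Further groups separated these gates. Medians were 0.95 for hypoxia and glycolysis (10 of 20 higher), 0.78 for glutathione and NRF2 targets (10 of 21), 0.998 for basal genes (8 of 16), 1.43 for chemokines and cytokines (9 of 16, including the neutrophil attractant Cxcl1) and 1.96 for transcripts of the sort gate (4 of 4, Itga6, Cd34, Cd44 and Pecam1, which encodes the excluded CD31). The p53 and cell cycle inhibitor list had a median of 1.14 (8 of 15), with Cdkn1a, which encodes p21, at 268.4 against 65.3 TPM. Immediate early genes were lower, 11 of 18, with a median of -1.25 and Fos at 143.1 against 357.7 TPM. Within the CD44-negative α6+ gate, medians of cells with Xist over those with Y-linked transcripts were 1.52 for interferon, 1.45 for MHC class II, 1.12 for immediate early, 0.85 for G2/M and 1.07 for MHC class I genes, lists that were also higher in the CD44+ gate. TGF-beta and SMAD response genes had a median of 0.16 (3 of 20 higher and 4 of 20 lower), -0.48 without plate CSC1, and co-signalling and immunosuppressive genes of -0.10 (5 of 17 higher and 5 of 17 lower). Bgn, a matrix proteoglycan, and Thy1, a fibroblast and lymphocyte surface gene, had log2 folds of -6.45 and -5.07, which were -1.42 and -2.61 without non-keratinocytes, where the G2/M median was -0.97 and that of the transition and stem-like list 2.30 in place of 0.18. Without plate CSC1 the transition list median was -0.71, that of MHC class I -1.67 and that of the sort gate 1.10. On the same step the matrix and protease median of 1.90 was 0.19, that of chemokines and cytokines 0.27 and the log2 fold of Mmp9 1.08 instead of 4.84, of Stra6 5.43 instead of 6.31 and of Bgn -5.54. Itga6 had a log2 fold of 1.55, and of 0.48 to 1.85 with 1 reporter-positive plate left out in turn, below 2-fold at the low end. Without CSC2 the suprabasal median was 0.78, and log2 folds were 2.49 for Slpi, 3.94 for Gsta1, 3.99 for S100a9 and 6.33 for Sprr1a instead of 7.14, 5.08, 4.81 and 7.21. Among libraries with 3000 to 6000 genes (6 and 3 cells) the G2/M median was -0.30 and that of chemokines and cytokines -0.64.

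Against CD44-negative α6+ cells, reporter-positive cells had higher transcripts of simple epithelial keratins, of part of the cornified envelope and of matrix and proteases. Klk6 was 140.7-fold, Cnfn 41.9-fold and Sprr1a 25.96-fold higher, log2 folds of 7.14, 5.39 and 4.70 that were 4.90, 3.75 and 3.81 without CSC2. The suprabasal median was 0.63, with 9 of 19 members higher and 6 of 19 lower, Krt1 and Krt10 among the lower ones. Krt18, a simple epithelial keratin, was 29.95-fold higher, and its partner Krt8 averaged 37.8 TPM while listed at 0 in the other gate. Lgals1, which encodes galectin-1, was 21.2-fold, Cldn4 20.9-fold and Arg1, an arginine-degrading enzyme, 18.8-fold higher. Matrix and protease genes were higher in 17 of 20 cases, with a median of 2.23, including the urokinase gene Plau at 296.7 against 37.9 TPM. Of the transition and stem-like list, 12 of 13 were higher, with a median of 2.15, including the chromatin factor Hmga2 at 22.8 against 1.55 TPM and the gate genes Cd44, 374.5 against 139.4, and Cd34, 5.51 against 0.553. Of the co-signalling and immunosuppressive genes, 6 of 15 were higher (Cd80, Cd276, Nt5e, Pvr, Arg1 and Ptgs2) and 2 of 15 lower (Cd200 and 4632428N05Rik, also known as Vsir), with a median of 0.93, and Nt5e, an ectoenzyme that makes adenosine, averaged 29.3 against 5.43 TPM.

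TGF-beta and SMAD response genes had a median of 0.53 in this comparison, 0.013 without plate CSC1, with 6 of 19 at least 2-fold higher and 0 lower, Cdkn2b, a TGF-beta-induced cell cycle inhibitor, averaging 29.2 against 4.37 and Tgfb1 itself 9.30 against 4.39 TPM. Inhibitors and p53 targets had a median of 0.76 (7 of 15 higher), with Cdkn1a at 268.4 against 73.02 and Cdkn2a, a tumour suppressor locus, at 16.2 against 2.31 TPM. Mitotic and S phase genes had medians of -0.78 and -0.71, with 7 of 22 and 7 of 20 lower, for example Mcm6 of the replicative helicase at 4.41 against 14.6 TPM. Lower named genes were Krt15, a keratin of basal and follicle stem cells, at 1.46 against 74.4 TPM, Krt10 at 7.14 against 122.97, Krt1 at 42.4 against 561.5, the BMP and WNT antagonist Sostdc1 at 3.37 against 69.4 and the aldehyde dehydrogenase Aldh3a1 at 1.11 against 36.3. MHC class II genes were lower, 5 of 6, with a median of -2.10. The interferon median of -0.44 was 1.05 against the Y-linked cells of the CD44-negative gate alone, where Ifi27l2a had a log2 fold of -1.13 instead of -6.18. Without CSC1 the medians were -1.16 for interferon, -2.91 for MHC class II, 0.88 for matrix and proteases, 1.42 for the transition list, 0.20 for basal genes and 0.26 for co-signalling. The log2 folds of Krt18, Cd34, Krt15 and Aldh3a1 were then 4.25, 1.42, -3.84 and -3.07 instead of 4.90, 2.07, -4.93 and -4.15. Among libraries with 3000 to 6000 genes (6 and 13 cells) the basal median went from 0.83 to -0.25, that of co-signalling to 0.13 and that of chemokines and cytokines from 1.18 to -1.42.

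The CD44+ reporter-negative and CD44-negative α6+ gates differ by surface CD44, although the Cd44 transcript was not higher in the CD44+ gate, at 73.1 against 139.4 TPM. Interferon-response genes were higher in the CD44+ gate, 19 of 23, with a median of 1.65. Examples were the ubiquitin-like Isg15 at 5.69 against 2.19 TPM, the interferon regulatory factor Irf7 at 12.5 against 3.44 and Bst2, an antiviral tether, at 27.3 against 7.995. The interferon-induced GTPase gene Tgtp2 had a log2 fold of 4.48, which was 2.18 without non-keratinocytes, and with Xist cells of the CD44-negative gate alone the interferon median was 1.12. TGF-beta and SMAD genes had a median of 0.49 (4 of 20 higher). MHC class I had a median of 0.95 (9 of 18 higher), immediate early genes of 1.07 (12 of 18) and G2/M genes of 0.71 (8 of 22), beside a median over all genes of 0.11. Suprabasal and stress keratin lists were lower, with medians of -1.28 (11 of 18) and -1.07 (6 of 11). S100a8, the other calprotectin subunit, averaged 15.8 against 137.6 TPM, Krt1 88.1 against 561.5, Sprr1b 22.4 against 120.4 and Gpx2, a glutathione peroxidase, 1.42 against 31.1. Mesenchymal genes led the higher side, with Vim, the mesenchymal intermediate filament, at 220.6 against 0.497 TPM, fibronectin Fn1 at 112.1 against 0.708 and Col4a1, a basement membrane collagen, at 98.7 against 0.160. Without the 3 non-keratinocytes the log2 folds were 2.72 for Vim, 0.22 for Fn1 and 0.11 for Col4a1, and the transition list median went from 1.73 to 0.057. Against the Xist cells of the CD44-negative gate alone, the suprabasal median was 0.40, the stress one 0.065 and the log2 folds of S100a8, Sprr1b, Krt1 and Gpx2 1.96, 0.054, -0.60 and -2.57. Among libraries with 3000 to 6000 genes (3 and 13 cells) the interferon median was 0.20, that of the transition list -0.40 and that of G2/M genes -1.01.

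Integrin α6 anchors basal keratinocytes to the basement membrane, and the CD44-negative α6+ gate was set beside the α6-negative gate to see what goes with it. Itga6 itself averaged 45.3 against 7.73 TPM. Basal keratinocyte genes were higher in α6+ cells, 11 of 16, with a median of 2.15. The hemidesmosome and laminin genes Col17a1, Itgb4 and Lamb3 averaged 116.8, 83.4 and 70.6 against 2.42, 4.66 and 0.0562 TPM, and Itga3, a laminin receptor chain, was 45.3-fold higher. Mitotic genes were higher in 21 of 22 cases and S phase genes in 13 of 20, with medians of 2.601 and 1.43, and Cdc20, an activator of mitotic exit, was listed at 0 in α6-negative cells. Glycolysis genes such as Ldha, 405.4 against 114.7 TPM, had a median of 1.15 (11 of 20), and the metallothionein Mt2 was 21.2-fold higher. Suprabasal genes were lower in α6+ cells, 11 of 20, with a median of -1.26, and the protease inhibitor Cst6 and the β-defensin Defb6 averaged 2.32 and 3.63 against 456.4 and 1531 TPM in α6-negative cells.

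The fibrillar collagen genes Col1a1 and Col3a1 were far lower in α6+ cells, Col1a1 at 0.526 against 1432 TPM and Col3a1 at 1.31 against 1319, and matrix and protease genes had a median of -3.20, with 16 of 20 lower. Fibroblast, pericyte or muscle markers led in 16 of the 42 α6-negative cells, and in keratinocytes alone the matrix and protease median was 1.63, the log2 fold of Col1a1 -1.09 and that of Col3a1 -0.15. The transition list moved from -2.88 to -0.53, co-signalling from -0.78 to 0.94 and stress keratins from 0.88 to 0.19. MHC class II and interferon medians were 2.53 and 1.02, the latter -0.82 with Y-linked α6+ cells alone and 1.67 in keratinocytes alone. The median over all genes was -0.29 here, the α6-negative cells had fewer genes, and among libraries with 3000 to 6000 genes (13 and 22 cells) the G2/M median was 1.53 and the stress keratin median -2.69.

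**Figure D2:**
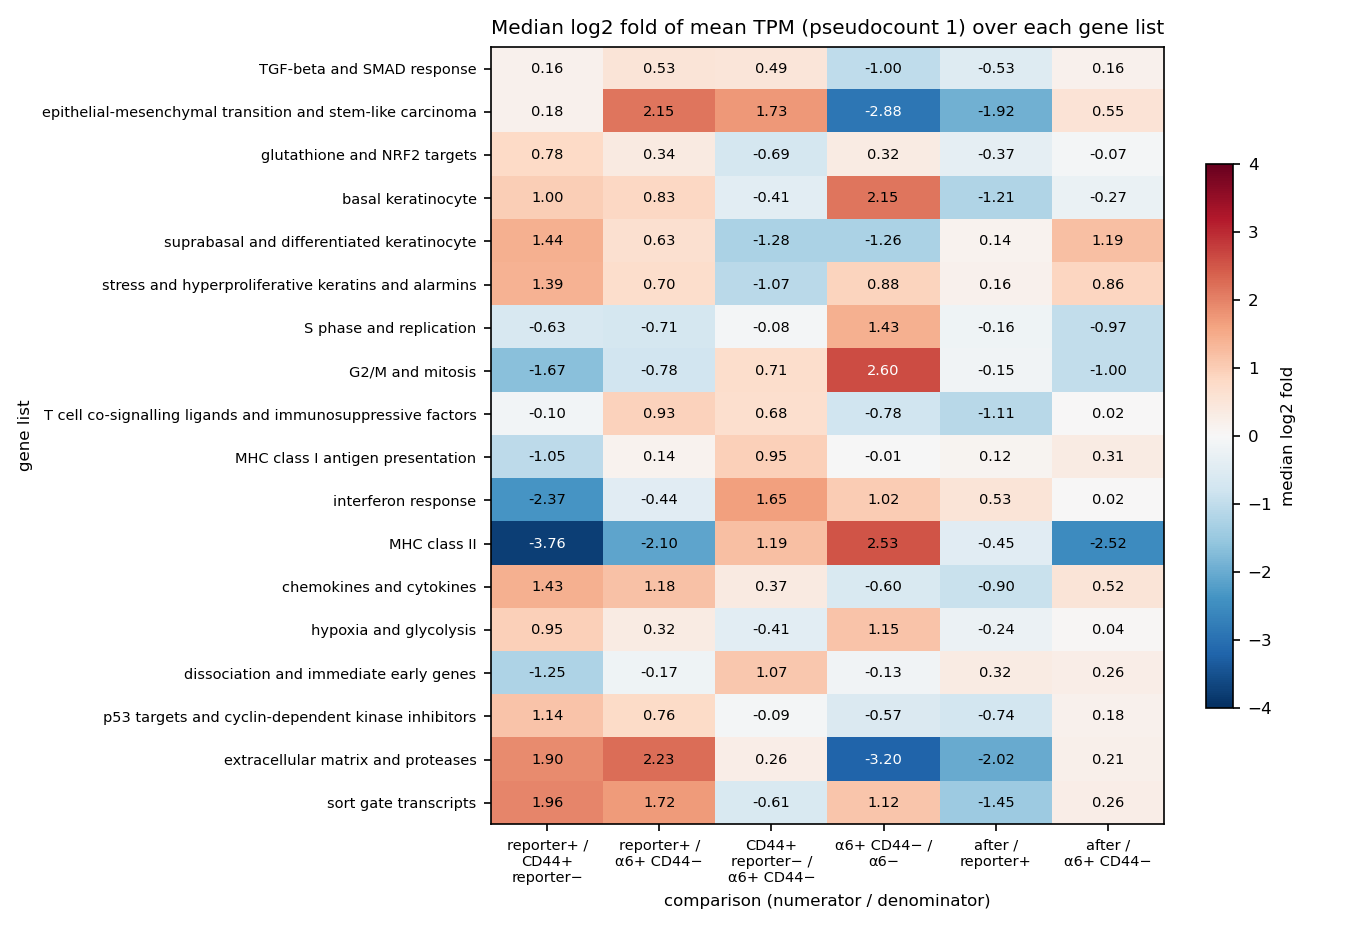
Median log2 fold of each gene list (rows) in the 6 comparisons (columns, first group over second), on a colour scale. Matrix and protease genes stood at 2.23 in reporter-positive over CD44-negative α6+ cells and at -2.02 in cells after transfer over reporter-positive cells.

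Cd80 encodes a ligand of the T cell receptors CD28 and CTLA-4 and is usually made by antigen-presenting cells. The gene (ENSMUSG00000075122) is protein coding and lies on the plus strand of chromosome 16, from 38455561 to 38496335 in mm10. It was detected in 75% of reporter-positive cells (65.6 to 82.97) at a mean of 8.44 TPM. Shares were 7.14% (0.181 to 33.9) in CD44+ reporter-negative, 8.79% (3.87 to 16.6) in CD44-negative α6+ and 2.38% (0.0603 to 12.6) in α6-negative cells. The log2 folds over the CD44+ reporter-negative and the CD44-negative α6+ gates were 2.76 and 2.54. Cd274, which encodes the checkpoint ligand PD-L1, was detected in 14.4% of reporter-positive (8.30 to 22.7), 14.3% of CD44+ reporter-negative (1.78 to 42.8) and 3.30% of CD44-negative α6+ cells (0.685 to 9.33). Detection of Cd80 went with the number of genes per cell, repeats merged: in reporter-positive cells it was found in 1 of 11 cells under 6000 genes, 43 of 57 with 6000 to 8000 and 34 of 36 above. With 6000 to 8000 genes, CD44-negative α6+ cells had 7 of 69, whereas among libraries with 3000 to 6000 genes, chosen before repeats were merged, 0 of 6 reporter-positive cells had the transcript and no difference was detectable. Without CSC1 the log2 folds were 1.96 and 1.74 and the reporter-positive share 62.5%.

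**Figure D3:**
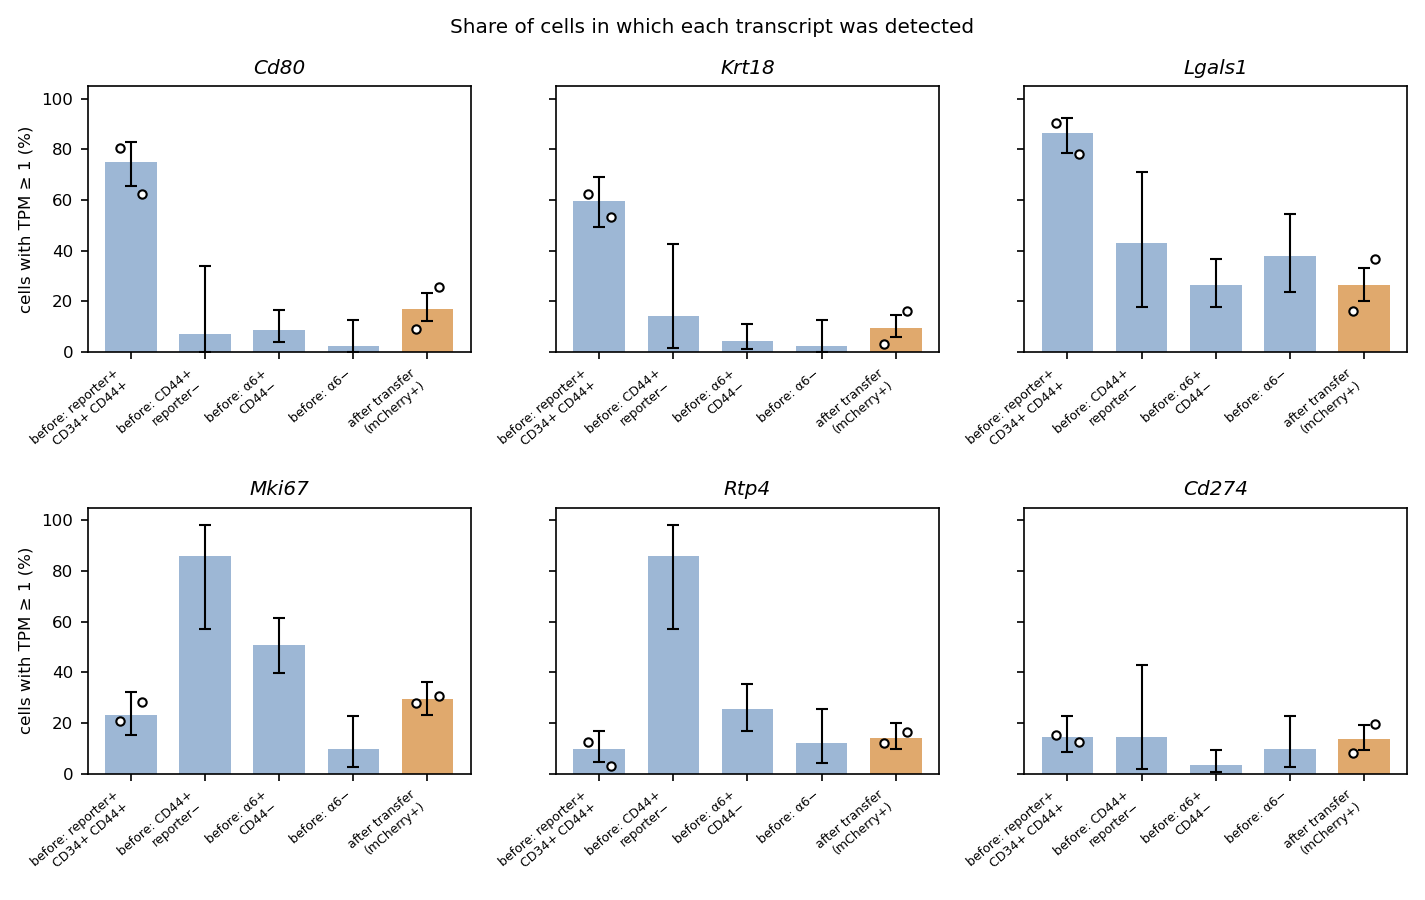
Percent of cells with a TPM of at least 1 for Cd80, Krt18, Lgals1, Mki67, Rtp4 and Cd274 in the 4 gates before therapy and in cells after transfer, with exact 95% intervals for counting error as error bars and plates as points where a group had more than 1. Cd80 was found in 75% of reporter-positive cells and 17.2% of cells after transfer.

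Cells after transfer were set beside reporter-positive cells to see which features cells present after therapy shared with them. Matrix and protease genes were lower after transfer in 18 of 19 cases, with a median of -2.02, among them the metalloproteinase inhibitor Timp1 at 0.884 against 17.4 TPM and Serpine2, a protease inhibitor, at 0.575 against 14.3. The transition list had a median of -1.92 (11 of 13 lower), with Vim at 2.53 against 25.3 TPM, and basal genes of -1.21 (9 of 16). Other lower genes were Klk6, 7.10 against 169.6 TPM, Stra6, 11.96 against 153.6, Inhba, which encodes the activin A subunit, 1.06 against 21.99, and the tubulin gene Tuba1a, 10.4 against 84.3. Higher after transfer were Krt10, 29.1-fold, Krt1 at 674 against 42.4 TPM, the desmosomal genes Dsc1 and Dsg1a, 7.02-fold and 6.37-fold, the chemokine gene Ccl8, 27.3-fold, and Ddr2, a collagen receptor, 8.64-fold. Krt10 was detected in 67.7% of cells after transfer and 65.4% of reporter-positive cells, and Ccl8 in 28.3% and 9.62%. Their means of log2(TPM + 1) differed by 2.58 and 1.14. The suprabasal list, which holds Krt10, Krt1, Dsc1 and Dsg1a, had a median of only 0.14. Of its members 7 of 19 were higher and 3 of 19 lower (Ivl, Sprr1a and Klk7). Co-signalling and immunosuppressive genes had a median of -1.11, with 9 of 15 lower, chemokines and cytokines of -0.90 (7 of 15 lower) and interferon genes of 0.53 (3 of 17 higher), while G2/M and S phase genes stood at -0.15 and -0.16 with 0 members past 2-fold. Cd80 was found in 17.2% of cells after transfer (12.2 to 23.2), a log2 fold of -2.10, with 9% on OT1/OT_B and 25.5% on OT2/OT_A, and Cd274 in 13.6% (9.18 to 19.2), with 8% on OT1/OT_B and 19.4% on OT2/OT_A.

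Strain, gate and table all changed together with therapy, so the groups cannot be compared for therapy alone, and the median over all genes was -0.19. Without plate CSC1 the medians were -0.77 for matrix and proteases, -0.84 for the transition list and -0.50 for basal genes, that of TGF-beta and SMAD genes went from -0.53 to 0.034 and the log2 folds of Timp1, Vim, Inhba, Cd80 and Dsc1 from -3.29, -2.89, -3.48, -2.10 and 2.81 to -1.28, -1.55, -2.01, -1.30 and 2.02. Smaller moves on the same step were those of Serpine2 to -2.62, Stra6 to -2.70 and Tuba1a to -2.17, while Klk6 went from -4.40 to -2.16 without CSC2 and Ccl8 from 4.77 to 3.83 without OT2/OT_A. Interferon genes stood at 1.37 without CSC1. Without OT2/OT_A the medians were -3.10 for matrix and proteases, -2.86 for the transition list and -1.52 for chemokines and cytokines. With all libraries as labelled the matrix and protease median was -1.02, the Cd80 share 34.7% and the log2 folds of Vim, Serpine2, Timp1 and Klk6 -0.22, -0.18, -1.09 and -1.47. Libraries added on that step mostly repeat cells of the reporter-positive and CD44+ gates. Many of the same cells then stand on both sides, so these values do not test the labels. Among libraries with 3000 to 6000 genes (58 and 6 cells) the log2 folds of Cd80, Vim, Tuba1a, Timp1 and Serpine2 were 0.062, 0.19, 0.88, 0 and -0.048. Cd80 was found in 0 of these 6 reporter-positive cells, so its fold there rests on the pseudocount and no difference was detectable.

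Beside CD44-negative α6+ cells, cells after transfer had more differentiation and stress transcripts. Only the former were sorted for α6, and strain and table changed too, so therapy cannot be told apart from these. Before therapy, α6+ over α6-negative cells had medians of -1.26 for suprabasal, 2.601 for G2/M, 1.43 for S phase and 0.88 for stress genes. All but the stress median have the sign that a missing α6 sort after therapy would give. Suprabasal genes had a median of 1.19, with 12 of 20 higher, and stress keratins and alarmins of 0.86 (5 of 11). Sprr1a averaged 280.2 against 22.1 TPM, Stfa2, which encodes a stefin protease inhibitor, 160.9 against 18.3, the exonuclease gene Trex2 53.9 against 5.76, Cst6 20.5 against 2.32 and Krt6b, a stress keratin that can share reads with Krt6a, 1815 against 602. Mitotic and S phase genes were lower, 11 of 22 and 5 of 20, with medians of -0.997 and -0.97 and a median over all genes of -0.10. MHC class II genes were lower in 6 of 6 cases, with a median of -2.52, Cd74 at 1.83 against 37.5 and H2-Ab1, a class II chain, at 1.98 against 21.2 TPM. Aldh3a1 at 0.508 against 36.3, the skin chemokine gene Ccl27a at 10.2 against 88.3 and the matrix gene Postn at 4.17 against 35.5 TPM were also lower. Yam1, a row that overlaps ribosomal sequence, met the rule for named genes, at 96795 against 15007 TPM. Against the Y-linked cells of the CD44-negative gate alone, the MHC class II median was -2.10 and Cd74 had a log2 fold of -3.07 rather than -3.77, Ifi27l2a of -0.19 rather than -5.23, Fcgbp, a mucin-like gene, of 0.10 rather than -3.24, Ccl27a of -1.35 rather than -2.998 and Postn of -1.22 rather than -2.82. Without OT1/OT_B the log2 folds of Cst6 and Yam1 were 1.76 and 1.88 instead of 2.69 and 2.69. Among libraries with 3000 to 6000 genes (58 and 13 cells) the G2/M median was 1.57, and with all libraries as labelled the MHC class II median was -1.34 and the log2 folds of Cd74 and Postn -2.22 and -0.85 instead of -3.77 and -2.82.

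Beside the remaining gates, Mki67 was detected in 29.3% of cells after transfer (23.1 to 36.2) against 85.7% in the CD44+ reporter-negative and 9.52% in the α6-negative gate. Cd34 averaged 1.13 TPM after transfer, 0.259 in the CD44+ reporter-negative and 10.5 in the α6-negative gate, where the log2 fold of CD44-negative α6+ over α6-negative cells went from -2.88 to -0.52 without non-keratinocytes. The mouse gene Hras averaged 72.4, 40.9, 56.97 and 55.3 TPM in the reporter-positive, CD44+ reporter-negative, CD44-negative α6+ and α6-negative gates and 62.4 after transfer. It stood at 53.8 on CSC1 and 114.3 on CSC2. No gene row belongs to the activated Hras transgene, and how many of its reads fell on the mouse gene is unknown. These values are therefore no measure of the transgene. The log2 fold of Hras in reporter-positive over CD44-negative α6+ cells was 0.34, 0.99 without CSC1 and -0.082 without CSC2, and for cells after transfer over reporter-positive cells -0.21, -0.86 and 0.21.

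By the genes that most set the gates apart (100 for each gate), 68.2% of cells after transfer were nearest to the CD44-negative α6+ gate (61.2 to 74.6) and 29.8% to the reporter-positive gate (23.5 to 36.7). By plate, 21% on OT1/OT_B and 38.8% on OT2/OT_A were nearest to the reporter-positive gate, the others mostly to the CD44-negative α6+ gate. Left out of their own gate's mean, 92.3% of reporter-positive, 80.2% of CD44-negative α6+ and 76.2% of α6-negative cells were nearest to their own gate, but only 6 of 14 CD44+ reporter-negative cells. With all libraries as labelled, 49.7% were nearest to the reporter-positive gate. The libraries this adds are mostly repeats of cells that make up the gate means, with 70 of 72 on OT_C nearest to the reporter-positive gate. That rise was therefore set by the pairing. With genes centred within each table the share nearest to the CD44-negative α6+ gate was 36.4%, and among libraries with 3000 to 6000 genes 53.4% were nearest to the reporter-positive gate.

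**Figure D4:**
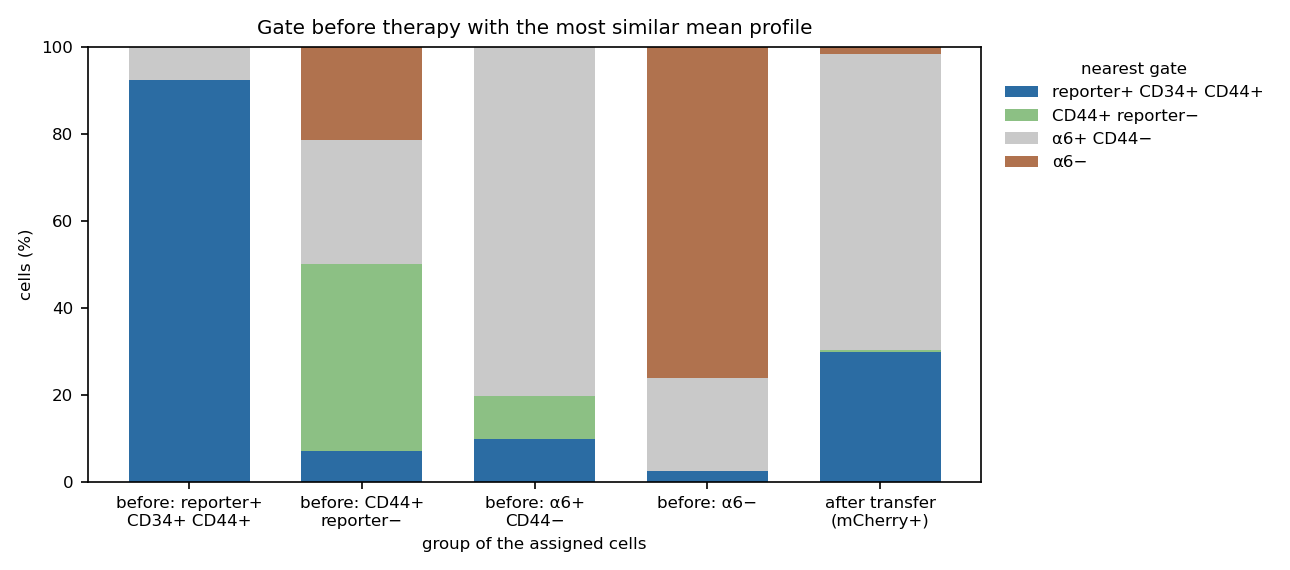
Percent of cells (vertical axis) of each group (horizontal axis) whose profile over the genes that most set the gates apart was most like the mean of each gate before therapy, by colour. Of the cells after transfer, 68.2% were nearest to the CD44-negative α6+ gate and 29.8% to the reporter-positive gate.

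Cells after transfer formed 4 clusters of 60, 57, 52 and 29 cells. Cluster 1 was led by genes that include the epidermal keratin Krt80 and Ly6g6c, and cluster 2 by the alarmin gene Il33, the gap junction gene Gjb2 and Krt6b. Cluster 3 was led by the basal genes Krt15, Lamb3, Itga3 and Itgb4, and cluster 4 by mitotic genes such as Ccnb1 and Plk1. Over the other cells after transfer, cluster 3 had medians of 2.98 for matrix and protease, 3.15 for transition and 4.73 for basal genes. The matrix and protease medians of clusters 1, 2 and 4 were -2.41, -2.72 and -2.91. Means of these lists after transfer thus depend on the share of cluster 3 cells. Cd80 was detected in 0 of 60 (upper limit 5.96%), 16 of 57 (28.1%, 16.97 to 41.5), 14 of 52 (26.9%, 15.6 to 41.02) and 4 of 29 cells (13.8%, 3.89 to 31.7). The median number of genes was 5432.5 in cluster 1 and 6933, 7508.5 and 7122 in the others, a gap that can set these shares.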

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

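The tests of the repeat libraries and of the interferon and MHC class II transcripts were chosen only after the result was seen.

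In the libraries of plates OT_C and OT_D, labelled after therapy and left out of the comparisons, Cd80 was detected in 76.4% (64.9 to 85.6) and 45.5% of cells (30.4 to 61.2), above the 17.2% of the other cells after transfer. Different cells that merely resemble each other are argued against, because 97.4% of the pairs across the labels lay in the same well. In OT_D, 100% of 30 wells with a sex-linked transcript (lower bound 88.4%) followed the division of the plate by rows between the reporter-positive and CD44+ reporter-negative gates, which the pairing itself sets for all but 3 of them. Plates sorted before therapy and sequenced again, and plates from after therapy listed a second time as before therapy, therefore cannot be told apart by these wells, nor by a transgene, since 0 genes of the tables belong to one. The 72 wells of CSC2 and the 24 of the CD44+ reporter-negative gate shared 0 well names and together made up 96. On OT_D 10 libraries had Xist, against 0 on each of OT1, OT2, OT_A and OT_B. These values do not settle the label. Which label is right stays open, and with all libraries as labelled the Cd80 share after transfer was 34.7%.

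Interferon-response and MHC class II transcripts were higher in the CD44+ reporter-negative than in the reporter-positive gate. Stromal cells within the gate are argued against as the whole cause, because the interferon and MHC class II medians of reporter-positive over CD44+ reporter-negative cells were -1.85 and -4.09 without non-keratinocytes. Another animal or sex may contribute: within the CD44-negative α6+ gate, cells with Xist had an interferon median 1.52 above that of cells with Y-linked transcripts and an MHC class II median 1.45 above, and the suprabasal, stress keratin, G2/M, immediate early and MHC class I lists, by which the CD44+ and reporter-positive gates also differ, had medians of -1.62, -0.77, 0.85, 1.12 and 1.07. Set beside those Xist cells alone, the CD44+ gate still had an interferon median 1.12 higher, whereas the MHC class II median was 0.032 in place of 1.19. Non-keratinocytes of the CD44+ gate were kept there, and no alternative left them out and matched sex together. Whether sex accounts for the whole distance in interferon genes from the CD44-negative gate is therefore not decided. The labels name no animal, so another animal, sex and a difference that belongs to the gate itself stay open.

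Cd80 was detected in fewer cells after transfer than in the reporter-positive gate. Over CD44-negative α6+ cells, in contrast, its log2 fold after transfer was 0.45 (-0.15 to 0.88 with plates left out in turn). For the cells sequenced here, the missing α6 sort after therapy is argued against as the whole cause. Cd80 was found in 26.9% of cells of the basal cluster, with an upper bound of 41.02% below the lower bound of 65.6% in reporter-positive cells. Fewer genes per cell are argued against as the whole cause for cells with 6000 to 8000 genes. There the shares were 19.2% (12.8 to 27.1) after transfer and 75.4% (62.2 to 85.9) in reporter-positive cells. The bounds in both checks cover counting error over cells, not the spread between plates or animals. Over all cells, Cd80 was found in 9% on OT1/OT_B and 25.5% on OT2/OT_A. On the reporter-positive plates CSC1 and CSC2 it was found in 80.6% and 62.5%. Many profiles after transfer merge repeat libraries, so equal gene numbers need not mean equal depth. Under 6000 genes Cd80 was found in 1 of 53 cells after transfer and 1 of 11 reporter-positive cells, with no difference detectable. Therapy, strain, the reporter, CD34 and CD44 in the gate and the separate tables changed together and stay open. With the libraries as labelled the log2 fold over reporter-positive cells was -0.995 instead of -2.10, with many of the same cells on both sides.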

How the results depend on the processing

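The alternatives with libraries as labelled, with repeats not merged, without ribosomal rows, with merged plates of cells after transfer left out, with cells chosen by Xist or Y-linked transcripts and with keratinocytes of 3000 to 6000 genes were chosen only after the data were seen, and so were the lists treated as leading results. Of 5000 alternative values, 3870 stayed within 1.5-fold or within the interval of a share, 1079 moved and 51 reversed. Part of those that stayed could hardly move. Rescaling shifted each comparison by less than 1.5-fold. Leaving out a single plate name after transfer kept most of the cells through their repeats. Leaving out non-keratinocytes changed no fold between groups that held none, and CSC2 alone repeated the step without CSC1. These counts are therefore no measure of robustness. Shares of cells with Cd80 were limited by the number of genes per cell, since detection was rare under 6000 genes. Values are list medians or gene folds on the log2 scale, or percent of cells, and where no reason is given the cause was not tested. No paired analysis was possible because replicate numbers only count wells in order of deposit and no test was run.

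Among libraries with 3000 to 6000 genes, few cells were left (6 reporter-positive, 3 CD44+ reporter-negative, 13 CD44-negative α6+, 22 α6-negative and 58 after transfer). The window was set on single libraries before repeats were merged, so a merged profile can hold more than 6000 genes or lack a repeat outside the window. Reporter-positive over CD44+ reporter-negative medians were 4.62 (suprabasal), -0.30 (G2/M), -3.14 (interferon), -6.02 (MHC class II), -0.64 (chemokines) and 2.58 (matrix). Over CD44-negative α6+ cells they were -0.25 (basal), 0.13 (co-signalling) and -1.42 (chemokines), and both Cd80 folds were 0. CD44+ reporter-negative over CD44-negative α6+ values were -0.40 (transition), -2.85 (suprabasal), -1.01 (G2/M), 0.20 (interferon), -1.61 (Art3), -0.78 (Col4a1), -0.55 (Mcam) and -1.21 (Vim). α6+ over α6-negative medians were -2.69 (stress), 1.53 (G2/M), 0.0088 (chemokines), -2.32 (matrix) and -1.78 (sort gate), and with keratinocytes alone -3.05 (stress), 1.496 (G2/M), 0.70 (co-signalling), -0.64 (matrix) and -1.08 (sort gate), with Cd80 in 0%. After transfer over reporter-positive values were 2.24 (interferon), -2.65 (matrix), 0.40 (Cd34), 0.062 (Cd80), 0.88 (Tuba1a) and 0.19 (Vim), and over CD44-negative α6+ cells -0.57 (transition), 2.07 (suprabasal), 1.57 (G2/M), -4.82 (MHC class II), -1.10 (chemokines) and 0.29 (Hist1h3b). Cd80 was found in 0% of cells in each gate before therapy and 3.45% after it, so its folds in this window rest on the pseudocount. Of cells after transfer, 53.4% and 18.97% were nearest to the reporter-positive and CD44-negative α6+ gates.

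Without non-keratinocytes, values were -0.97 (G2/M) and 2.95 (matrix) for reporter-positive over CD44+ reporter-negative cells. For CD44+ reporter-negative over CD44-negative α6+ cells they were 0.057 (transition), -1.32 (Art3), -0.44 (Col4a2), -0.85 (Mcam) and -2.04 (Serpine2). For α6+ over α6-negative cells they were 3.29 (G2/M), 0.94 (co-signalling), 1.63 (matrix) and 0.94 (Tgfb1), Cd80 was found in 0% of α6-negative cells, and 48.5% of cells after transfer were nearest to the CD44-negative α6+ gate. With Xist cells of the CD44-negative α6+ gate alone, CD44+ reporter-negative cells differed by 0.40 (suprabasal), 0.065 (stress), 1.96 (S100a8), 0.054 (Sprr1b) and 0.79 (Them5). With its Y-linked cells alone, values were 2.93 (matrix, reporter-positive over these), 2.91 (interferon, CD44+ reporter-negative over these), -0.82 and -4.13 (interferon and matrix over α6-negative cells) and 0.10 (Fcgbp, after transfer over these), with Cd80 in 3.23%. With all libraries as labelled, after transfer over reporter-positive values were -0.81 (transition), -1.02 (matrix) and -0.995 (Cd80), MHC class II over CD44-negative α6+ cells was -1.34, Cd80 was found in 34.7%, and 49.7% and 45.5% were nearest to the reporter-positive and CD44-negative α6+ gates. On that step many of the same cells stood both after transfer and in the reporter-positive gate.

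With all deposited cells, however few their genes, reporter-positive over CD44+ reporter-negative medians were 0.062 (suprabasal), -1.72 (interferon) and -3.09 (MHC class II). CD44+ reporter-negative over CD44-negative α6+ values were -0.21 (suprabasal), 0.048 (stress), 1.05 (interferon), 0.23 (sort gate), 0.11 (S100a8) and 0.038 (Sprr1a), the stress median of α6+ over α6-negative cells was -0.26, reporter-positive Cd80 49.7% and the share nearest to the reporter-positive gate 23.04%. With genes centred within each table, cells nearest to the CD44-negative α6+ gate made up 36.4%. With detection at a TPM of at least 10, Cd80 was found in 28.8% of reporter-positive, 0% of CD44+ reporter-negative, 1.10% of CD44-negative α6+ and 0% of α6-negative cells and 3.03% after transfer.

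In the order of the 6 comparisons, means of log2(TPM + 1) gave 0.59 (suprabasal), -1.56 (interferon), -1.24 (MHC class II) and 0.83 (matrix), then 1.45 (matrix), then 0.65 (transition), then 3.11 (basal), 1.37 (G2/M), 0.023 (co-signalling), 0.14 (chemokines), 0.00024 (p53), -0.89 (matrix) and 0.075 (Tgfb1), then -2.48 (basal) and -0.61 (MHC class II). With a pseudocount of 10, folds shrank by construction: 0.81 (suprabasal), -0.89 (G2/M), -1.16 (interferon), -2.0004 (MHC class II), 0.89 (matrix) and 0.83 (Cd80), then 1.51 (transition), 0.31 (co-signalling), 1.10 (matrix) and 0.80 (Cd80), then 0.31 (transition), -0.36 (suprabasal) and 0.74 (interferon), then 1.48 (basal), 0.90 (G2/M) and -1.67 (matrix), then -1.30 (transition), -0.39 (co-signalling), -1.201 (matrix) and -0.72 (Cd80), then -0.80 (MHC class II). With a pseudocount of 0.1 they grew to -2.97 (interferon) and 4.12 (Cd80), 3.57 (Cd80), 3.91 (transition), 3.38 (G2/M), -2.71 (Cd80) and -3.29 (MHC class II). With all members of each list, medians were 0.63 (suprabasal) and -2.59 (MHC class II), 1.39 (transition) and 0.23 (co-signalling), 1.06 (transition), and -0.89 (transition) and -0.13 (co-signalling). With members of at least 10 TPM they were -4.42 (MHC class II), -0.86 (sort gate) and -1.10 (chemokines).

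With plates left out in turn, reporter-positive over CD44+ reporter-negative values ranged over 0.78 to 1.89 (suprabasal), 0.19 to 2.35 (matrix) and 1.96 to 3.01 (Cd80), with matrix at 0.19 and Cd80 at 1.96 for CSC2 alone. Over CD44-negative α6+ cells they ranged over 1.42 to 2.595 (transition), 0.26 to 0.97 (co-signalling), 0.88 to 2.61 (matrix) and 1.74 to 2.79 (Cd80). After transfer over reporter-positive ranges were -0.65 to 0.034 (TGF-beta), -2.86 to -0.84 (transition), -1.54 to -0.50 (basal), 0.31 to 1.37 (interferon), -3.10 to -0.77 (matrix) and -2.70 to -1.30 (Cd80), and over CD44-negative α6+ cells -0.13 to 1.19 (transition) and -0.070 to 0.61 (chemokines), the low ends of the last pair without OT2/OT_A. Cd80 was found in 62.5 to 80.6% of reporter-positive cells and 9 to 25.5% after transfer, and 19.2 to 43.9% and 53.03 to 79.3% of cells after transfer were nearest to the reporter-positive and CD44-negative α6+ gates.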

Other observations

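The comparison by sex-linked transcripts and that of repeat libraries were chosen only after the data were seen. The CD44-negative α6+ gate held 23 cells with Xist and 31 with Y-linked transcripts, and their profiles differed in several gene groups. Interferon-response genes were higher in the cells with Xist, 16 of 21 by at least 2-fold, with a median log2 fold of 1.52, and MHC class II and class I genes had medians of 1.45 and 1.07. Ifi27l2a was 90.8-fold higher, the antiviral enzyme gene Oas1a averaged 17.97 against 1.197 TPM and Stat2, a transducer of type I interferon signals, 5.16 against 0.368. Suprabasal genes were lower in the cells with Xist, 12 of 17, with a median of -1.62, Krt10 averaging 16.3 against 156.5 and S100a8 3.31 against 159.2 TPM. Matrix and protease, immediate early and G2/M genes had medians of 1.51, 1.12 and 0.85. No animal is named, so these are differences between cells of at least 1 female and 1 male animal.

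Repeat libraries of 1 cell under different plate names gave the same Cd80 call in 92.1% of pairs, with 95 pairs detected in both libraries and 19 in 1 library only. Every pair in which both libraries had a sex-linked transcript carried transcripts of the same sex.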
